A study of Homo sapiens with 4 samples.

How the data were processed

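Messenger RNA was sequenced from MDA-MB-231 cells, an established human triple-negative breast cancer line, after 24 h with the compound YW-LF or with its solvent control, dimethyl sulfoxide (DMSO). Per the labels' protocols, the cells grew with 10% fetal bovine serum, RNA was taken with a Qiagen RNeasy kit, and 1.4 µg of total RNA went into a Hieff NGS mRNA library kit for Illumina sequencing. The series title calls YW-LF a derivative of ribociclib, an inhibitor of the cell cycle kinases CDK4 and CDK6. The dose of YW-LF is not given in the sources used here. There were 4 libraries, 2 per group, and groups were taken from the labels. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

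The authors deposited whole-number read counts per gene, without normalization, as the values themselves show. The aligner, the counting program and the annotation are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas all 20263 row identifiers of the table are human Ensembl genes and 0 are mouse genes. Counts were used by human identifier. Gene symbols came from a reference table that matched 20148 identifiers. The other 115 rows held 0.102% of counts and stayed in the tests. Of all rows, 19722 are protein-coding genes in the GENCODE 29 annotation of GRCh38, and coordinates are quoted from that annotation only, matched by identifier. A second count table of the authors held the same DMSO values (40526 of 40526 values identical), so it added no alternative for the comparison. The files hold 2 further columns of per-sample values that match no label; these were not used.

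Total counts per library were 34774542 and 37754168 for DMSO replicates 1 and 2, and 40218240 and 36886858 for YW-LF replicates 1 and 2. At these depths 1 count equals 0.0249 to 0.0288 CPM (counts scaled to a common library total). Counting error is large for MAP1LC3B2 and RSAD2, with at most 7 and 11 counts in a DMSO library, and for FAP, at 0.053 and 0.090 CPM in DMSO. For each other gene named by the rule below, at least 1 library of the lower group held 49 counts or more. Replicates of a group differed far beyond sampling noise (chi-square per degree of freedom 257 for the DMSO pair and 596 for the YW-LF pair), so no library was a copy of another.

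The main test was edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr (13816 genes), trimmed mean of M-values (TMM) scaling, a quasi-likelihood F-test of YW-LF against DMSO over all 4 libraries without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of its F statistic. CPM values are TMM-scaled; log2 CPM used a prior count of 2. Before the data were examined, 34 gene lists were fixed from textbook knowledge. Each was tested against all other genes with camera (limma 3.58.1, two-sided, preset inter-gene correlation 0.01), adjusted over the 34 lists. Camera with an estimated correlation and fry served as alternatives. With 2 libraries per group, the estimated form rests on few degrees of freedom and may be unable to call a list. Members past the threshold were counted over all genes tested and after adjustment over the list alone.

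The rule for the genes to be named was also fixed beforehand. Part (a) took the 8 strongest genes per direction among those past the threshold with a mean CPM of at least 5 and no overlap of the groups. Part (b) took 9 genes whatever their values: CDKN1A, MDM2, CDK4, CDK6, CCND1, RB1, CCNE2, MKI67 and 1 gene that is not reported here. Part (c) took the 3 members of lowest p in each list past the camera threshold or with at least 3 members past the threshold over all genes. Part (d) took the 4 members of lowest p in the p53, G1/S and G2/M lists. Part (a) gave no gene. In its place, and chosen after seeing the data, the 8 genes per direction of lowest unadjusted p with the same CPM minimum and no overlap were named. The parts together named 75 genes besides that one.

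The alternatives set beforehand were DESeq2 1.42.0, other scalings (DESeq2 size factors, upper quartile, library size only), other count filters (a total count of at least 1; at least 10 counts in all 4 samples), limma-voom, robust quasi-likelihood, a test against a 1.5-fold change, a threshold of 0.01, the replicate number as a block, and leaving out each library in turn (with the count filter applied anew, so the number of list members measured can differ). Added after seeing the data were the removal of the 13 mitochondrially encoded genes, limma-voom with sample quality weights, and a correction for transcript length and GC content. DESeq2 adjusted p-values given as missing stayed missing.

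The tests were first run on simulated data made from the means and library sizes of these 4 libraries for YW-LF against DMSO (13816 genes). With the spread seen over all 4 libraries, changes of 2-fold were recovered in 0% of genes, of 4-fold in 30%, of 8-fold in 78% and of 16-fold in 80%, with 11 false calls among 105. With the spread seen between the 2 DMSO libraries, the shares were 18%, 98%, 100% and 100%, with 6 false calls among 164. In the same data camera gave an unadjusted p of 0.038 (spread of all 4 libraries) and 0.53 (spread of the DMSO libraries) for 1 list of 40 unchanged genes. Of 1000 such lists, 1% and 0.5% had an unadjusted p under 0.05. The simulated genes vary independently, so these shares do not cover lists whose members vary together. Both simulated groups had the same spread, and 50 genes were changed at each fold. In the data the log2 ratio between replicates had an SD of 0.46 in DMSO and 1.09 in YW-LF, and 0 genes passed the main test. The recovery shares therefore do not describe how many true changes the test finds in these data.

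Reads shared between near-identical genes cannot be assigned with certainty when the counting method is unknown. Values of histone genes, metallothionein genes, ribosomal protein genes, MAP1LC3B2 (a near copy of MAP1LC3B) and the overlapping pair MT-ATP8 and MT-ATP6 are uncertain in this respect. Whether strand was used in counting is not given in the sources used here, so reads of overlapping antisense genes may be mixed into any gene. SOD2 and H3C2, members of fixed lists, were not analysed here.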

Results

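Gene expression was measured by RNA sequencing in MDA-MB-231 human breast cancer cells given YW-LF, a derivative of the CDK4/6 inhibitor ribociclib, for 24 h (n = 2) and in cells given DMSO (n = 2). The series title names activation of the p53 pathway, and the comparison asks which genes differ between the groups. Each library held 34774542 to 40218240 counts. The DMSO libraries resembled each other closely, with a Pearson correlation across 13816 genes of 0.976 in log2 CPM (genes are not independent replicates). The YW-LF libraries correlated less well with each other, at 0.907, and YW-LF replicate 1 was nearer to the DMSO libraries (0.922 and 0.911) than to YW-LF replicate 2, which stood at 0.865 and 0.859 with DMSO. The log2 ratio between replicates had an SD over 10809 genes of 0.46 in DMSO and 1.09 in YW-LF, so the treated libraries differed from each other far more than the controls did. Mitochondrially encoded genes took 8.68% and 21.7% of counts in DMSO replicates 1 and 2, and 3.14% and 6.58% in YW-LF replicates 1 and 2.

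Lists of G1/S and mitotic genes ranked below other genes in cells given YW-LF, and lists of inflammatory, immediate early, integrated stress response and unfolded protein response genes ranked above them, in camera with a preset correlation. Their adjusted p was 0.0098 or less (adjusted p = 0.44 with an estimated correlation). With 2 libraries per group the estimated form rests on few degrees of freedom and may be unable to call a list. Its p-values, here and below, therefore do not decide whether a list differs. The estimated correlations of these lists, 0.030 to 0.287, lay above the preset 0.01, so the preset p-values may be too small. Fry's test of direction called 0 lists, and camera did not call the lists of cyclins and CDKs, heat shock proteins or NRF2 targets. CCNE2 (cyclin E2, which drives entry into S phase; ENSG00000175305, chromosome 8, 94879770 to 94896678 in GRCh38) was 16.9-fold lower, with 61.1 and 58.9 CPM in the DMSO libraries and 4.24 and 2.85 CPM in the YW-LF libraries. IL1A (an inflammatory cytokine; ENSG00000115008, chromosome 2, 112773915 to 112784590) was 54.4-fold higher, with 1.25 ± 0.080 CPM in DMSO and 68.3 ± 40.3 CPM in YW-LF (mean ± SD, n = 2 each, as for all such values). CDKN1A (the CDK inhibitor p21; ENSG00000124762, chromosome 6, 36676460 to 36687339) was 5.36-fold higher. No single gene passed adjustment over all genes: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower, and its lowest adjusted p was 0.117, shared by 25 genes. At an unadjusted p under 0.05 there were 1585 genes higher and 1245 lower against 691 by chance in all, and 2614 of these 2830 differed at least 2-fold. With library size as the only scaling this split was 1489 higher and 755 lower. Both YW-LF libraries lay above both DMSO libraries in 3863 genes and below them in 3841, together 55.8% of genes tested, where chance gives 33.3%. DESeq2 called 841 genes higher and 623 lower, and 0 of those also tested in edgeR had the opposite sign there. Without a count filter edgeR called 155 genes higher and 120 lower, and with the replicate number as a block 186 and 145. CCNE2 (adjusted p = 0.013 and 0.0053), MKI67 (0.040 and 0.033) and CDKN1A (0.041 and 0.023) passed in both. These genes did not pass in edgeR with another scaling or the stricter count filter, or in limma-voom without sample quality weights. The labels tie the replicate numbers to no batch. The number of calls changed when 1 library was left out. In such a fit the remaining pair alone sets the spread. Member counts given below for these fits therefore reflect that pair as well as the treatment.

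The fold changes of the treated libraries went the same way for many genes. When each YW-LF library was compared with a different DMSO library, the log2 ratios correlated across genes with r = 0.49, and with r = 0.46 after the DMSO libraries were exchanged. The plot of these ratios shows the G1/S genes low in both libraries, and the ribosomal protein genes high along the axis of YW-LF replicate 2.

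**Figure D1:**
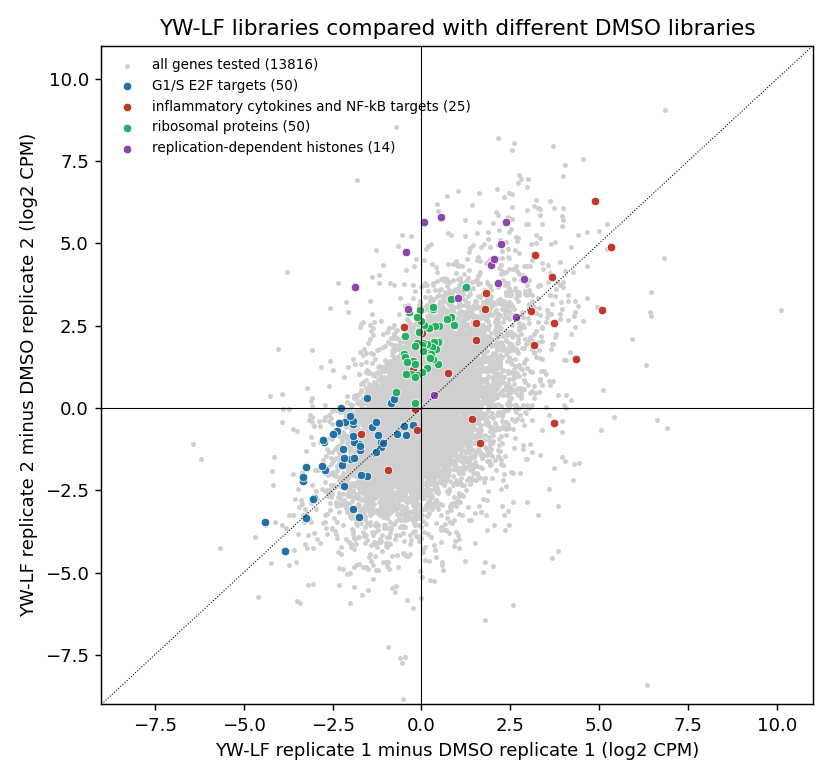
Each point is 1 of 13816 genes; the horizontal axis gives the log2 CPM difference of YW-LF replicate 1 from DMSO replicate 1 and the vertical axis that of YW-LF replicate 2 from DMSO replicate 2, with 4 gene lists in colour and equality as a dotted line. The ratios correlate with r = 0.49, and the ribosomal proteins have a median of 1.82 in YW-LF replicate 2 against 0.17 in YW-LF replicate 1 (each against the DMSO mean).

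Of 50 genes that act at the G1/S transition and in DNA replication, both YW-LF libraries lay below both DMSO libraries in 46 and above them in 0. The median log2 fold change was -1.38. Adjusted over the list alone, 29 were lower, 0 were higher and 21 passed in neither direction; over all genes tested, 0 passed. Besides CCNE2 (log2 fold change -4.08, SE 0.43), the members of lowest p were UHRF1 (-3.86, SE 0.48), which keeps DNA methylation through replication, CLSPN (-3.32, SE 0.39), a replication checkpoint protein, and MCM3 (-2.88, SE 0.39), part of the replicative helicase. Each had an adjusted p of 0.117 in edgeR over all genes. The list ranked below other genes in camera (adjusted p = 1.6e-17), but not with an estimated correlation (adjusted p = 0.44 with an estimated correlation). The count of lower members adjusted over the list alone was 14 without DMSO replicate 1 and 18 without DMSO replicate 2, 36 without YW-LF replicate 1 and 46 without YW-LF replicate 2.

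Of 46 G2/M and mitosis genes, both YW-LF libraries were below both DMSO libraries in 39 and above them in 1 (CKS2, chosen after its value was seen, at 1.55, SE 0.65), and the median log2 fold change was -0.89. MKI67, the proliferation marker Ki-67, was 6.33-fold lower, at 1431 ± 88.5 CPM in DMSO and 226 ± 8.49 CPM in YW-LF. MYBL2, a transcription factor of the cell cycle, was at -2.98 (SE 0.41), ANLN and KIF20A, both needed in cytokinesis, at -2.43 (SE 0.41) and -2.42 (SE 0.44), and the spindle checkpoint kinase BUB1B at -2.00 (SE 0.37). Adjusted over the list alone, 20 members were lower and 0 higher, with 0 over all genes tested. The camera test gave an adjusted p of 9.6e-10 (adjusted p = 0.44 with an estimated correlation), and 2 members passed over the list alone when DMSO replicate 1 or DMSO replicate 2 was left out, against 26 lower and 4 higher without YW-LF replicate 1 and 34 lower without YW-LF replicate 2. Of 30 DNA repair genes, 19 lay below DMSO in both libraries and 2 above, with a median of -0.86, led by the Fanconi anaemia helicase BRIP1 (-1.73, SE 0.35), BRCA1 (-1.72, SE 0.44) and the mismatch repair gene MSH6 (-1.52, SE 0.39). No repair gene passed over the list alone with all libraries, against 14 lower and 3 higher without YW-LF replicate 1 and 16 lower without YW-LF replicate 2, and the list had a camera adjusted p of 6.1e-04 (adjusted p = 0.44 with an estimated correlation).

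The targets and partners of CDK4/6 inhibitors showed no common direction. Among 18 measured cyclins, CDKs, inhibitors and RB family members the median was -0.06, a sign that turned with the length and GC correction (0.011), and 0 passed over the list alone (5 higher and 4 lower without YW-LF replicate 1, 4 higher and 6 lower without YW-LF replicate 2). The median was 0.056 without DMSO replicate 1, -0.17 without DMSO replicate 2, 0.028 without YW-LF replicate 1 and -0.435 without YW-LF replicate 2. CCND1, cyclin D1, was at 878 ± 114 CPM in DMSO and 320 ± 11.5 CPM in YW-LF (log2 fold change -1.46, SE 0.45, edgeR adjusted p = 0.164, DESeq2 adjusted p = 0.018). RB1, the retinoblastoma protein gene, was at -0.68 (SE 0.37) and CDK4 at 1.02 (SE 0.48). CDK4 stood at 69.5 CPM in YW-LF replicate 1 and 160 CPM in YW-LF replicate 2, against 55.4 and 58.2 CPM in DMSO. Its log2 fold change was 1.49 without YW-LF replicate 1 and 0.28 without YW-LF replicate 2. CDK6 was at 0.18 (SE 0.51), and its sign turned without YW-LF replicate 2 (-0.63) and without DMSO replicate 2 (-0.057). The list was not called in camera (adjusted p = 0.63).

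Genes of the p53 list went both ways. CDKN1A stood at 26.3 ± 10.6 CPM in DMSO and 141 ± 37.0 CPM in YW-LF (log2 fold change 2.42, SE 0.46, edgeR adjusted p = 0.121, DESeq2 adjusted p = 1.3e-04). The stress cytokine GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) was at 4.05 (SE 0.48), SESN2, a stress-induced regulator of metabolism, at 2.70 (SE 0.49), PMAIP1, the proapoptotic protein NOXA, at 2.56 (SE 0.43), and SERTAD1, a regulator of CDK4 and E2F activity, at 2.37 (SE 0.39). MDM2, the ubiquitin ligase that p53 induces, was at 56.4 ± 29.3 CPM in DMSO and 89.5 ± 12.5 CPM in YW-LF (0.67, SE 0.46, edgeR adjusted p = 0.443). Its log2 fold change was 0.23 without DMSO replicate 1 and 1.31 without DMSO replicate 2.

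Of the 43 measured p53 targets, 14 lay above DMSO in both YW-LF libraries and 9 below. Together this is a share no higher than the 55.8% over all genes tested. The median log2 fold change was 0.22, and ranged from 0.17 to 0.44 over the scalings and corrections tried. Adjusted over the list alone, 6 were higher (GDF15, SERTAD1, PMAIP1, SESN2, CDKN1A and the death receptor TNFRSF10B), 1 was lower (POLH, a translesion DNA polymerase at -1.63) and 36 passed in neither direction; over all genes tested, 0 passed. TNFRSF10B and POLH are outside the naming rule and were chosen after their values were seen. The list as a whole did not stand above other genes (camera adjusted p = 0.101, and 0.61 with an estimated correlation). Fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 2.9e-04. That test does not compare a list with other genes and called 18 of the 34 lists, so it does not set the p53 list apart. The median was 0.51 in YW-LF replicate 1 and -0.083 in YW-LF replicate 2 against the DMSO mean. In fits that left out 1 library it was 0.37 without DMSO replicate 1, -0.105 without YW-LF replicate 1 and 0.50 without YW-LF replicate 2. The camera adjusted p was 0.013 without YW-LF replicate 2 and 0.956 without YW-LF replicate 1. Over the list alone 1 member was higher and 0 lower without DMSO replicate 1 or without DMSO replicate 2, 10 higher and 7 lower without YW-LF replicate 1, and 12 higher and 4 lower without YW-LF replicate 2.

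**Figure D2:**
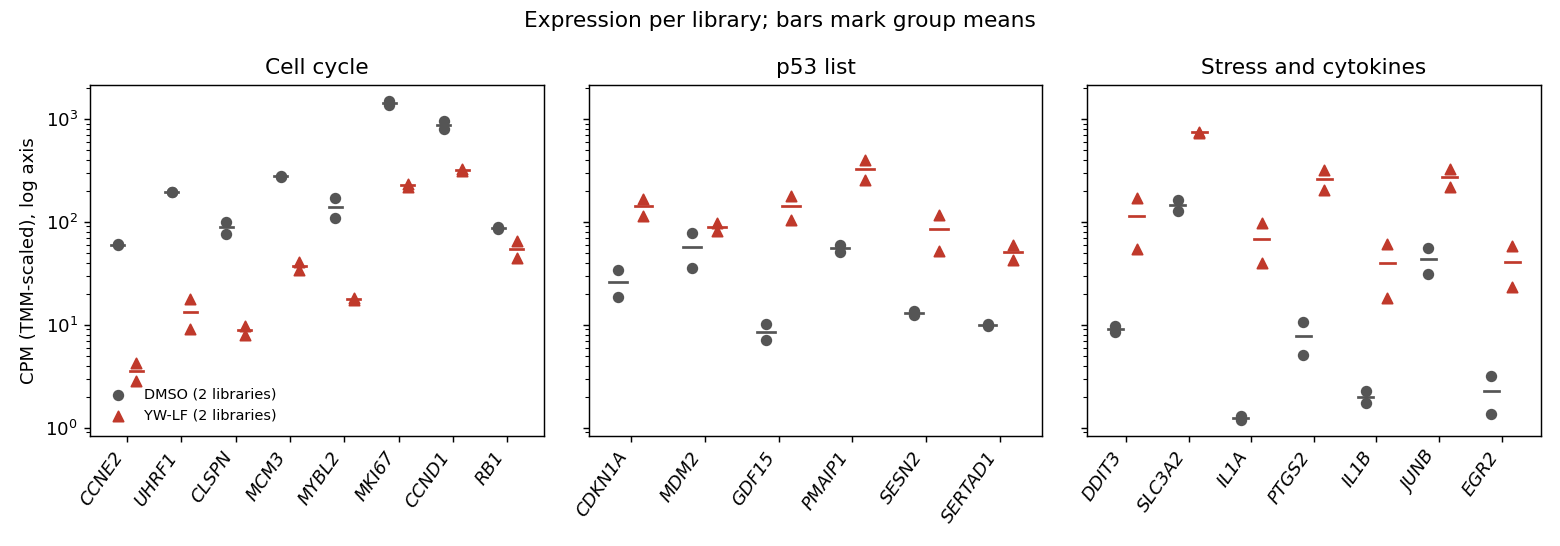
TMM-scaled CPM on a log axis for each of the 4 libraries, with grey circles for DMSO, red triangles for YW-LF and horizontal bars at group means, for genes of the cell cycle, of the p53 list, and of stress and cytokine lists. CCNE2 lies at 58.9 and 61.1 CPM in DMSO and at 2.85 and 4.24 CPM in YW-LF, whereas MDM2 lies at 35.7 and 77.2 CPM in DMSO and 80.7 and 98.3 CPM in YW-LF.

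Some inflammatory and immediate early genes were higher over the list alone. Of 25 measured cytokines and NF-kB targets, 14 lay above DMSO in both libraries and 3 below, and the median log2 fold change was 2.49. PTGS2, the prostaglandin synthase COX-2, was at 7.84 ± 3.91 CPM in DMSO and 262 ± 80.4 CPM in YW-LF (5.06, SE 0.58), and IL1B, another interleukin 1 gene, at 4.30 (SE 0.69). Adjusted over the list alone, 14 were higher, 1 was lower and 10 passed in neither direction, with 0 over all genes tested. Of 25 immediate early and AP-1 genes, 13 were higher and 2 lower over the list alone, with a median of 1.55. The transcription factor EGR2 was at 4.16 (SE 0.69), the AP-1 subunit JUNB at 2.64 (SE 0.48) and the nuclear receptor NR4A1 at 2.43 (SE 0.45). The camera adjusted p was 3.2e-06 for the cytokine list and 6.1e-04 for the immediate early list (both adjusted p = 0.44 with an estimated correlation). Without DMSO replicate 1 the counts of higher members over the list alone were 8 and 1, and without YW-LF replicate 1 they were 18 and 15, with 2 and 5 lower. The cytokine median was 1.41 without YW-LF replicate 2.

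Of 31 interferon-stimulated genes measured, 18 lay above DMSO in both libraries and 2 below. The median log2 fold change was 0.72 (0.42 with the length and GC correction). IFIH1 (the RNA sensor MDA5) was at 2.59 (SE 0.40), OASL at 2.20 (SE 0.38) and RSAD2 (viperin) at 4.16 (SE 0.72), the last from only 0.24 ± 0.081 CPM in DMSO. Over the list alone, 9 were higher, 1 was lower and 21 passed in neither direction, with 0 over all genes tested. The camera adjusted p was 6.2e-04 (adjusted p = 0.44 with an estimated correlation). Without YW-LF replicate 1 it was 0.095 and the median was 0.47. Over the list alone 0 members passed without DMSO replicate 1 or without DMSO replicate 2, against 12 higher and 4 lower without YW-LF replicate 1 and 13 higher and 2 lower without YW-LF replicate 2.

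Some genes of the integrated stress response, which ATF4 controls, were higher over the list alone. DDIT3, the transcription factor CHOP, was at 9.14 ± 0.97 CPM in DMSO and 113 ± 82.6 CPM in YW-LF (3.62, SE 0.62), SLC3A2, the heavy chain of amino acid transporters, at 2.34 (SE 0.45), and SESN2, which this list shares with the p53 list, at 2.70 (SE 0.49). Of 30 members, 9 were higher, 1 was lower and 20 passed in neither direction over the list alone, with 0 over all genes tested and a median of 0.67. Among 24 unfolded protein response genes 0 passed over the list alone and the median was 0.49; the stress sensor ERN1 (IRE1) was at 2.59 (SE 0.53), its target XBP1 at 1.25 (SE 0.39) and SELENOS at 1.06 (SE 0.35). The camera adjusted p was 6.1e-04 for the first list and 0.0098 for the second (both adjusted p = 0.44 with an estimated correlation). Over the list alone the counts of the first list were 4 higher and 1 lower without DMSO replicate 1, 3 higher and 0 lower without DMSO replicate 2, 12 higher and 3 lower without YW-LF replicate 1, and 13 higher and 1 lower without YW-LF replicate 2. The second list was lost without DMSO replicate 1 (0.054) and without YW-LF replicate 1 (0.122; median 0.26), and 4 of its members were higher over the list alone without YW-LF replicate 1 and 8 without YW-LF replicate 2.

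The median log2 fold changes of the lysosome and autophagy lists were positive and that of the fatty acid synthesis list negative. Of 31 lysosome genes, 20 lay above DMSO in both libraries and 1 below (median 0.68), among them the proton pump subunit ATP6V1B2 (1.60, SE 0.46), the sialidase NEU1 (1.17, SE 0.35) and the hexosaminidase HEXA (1.16, SE 0.38). Of 22 autophagy genes, 2 were higher over the list alone (median 0.68): the autophagosome protein gene MAP1LC3B, at 68.6 ± 13.2 CPM in DMSO and 328 ± 109 CPM in YW-LF (2.26, SE 0.45), and its near copy MAP1LC3B2 (3.53, SE 0.82), at 1.85 CPM in YW-LF and uncertain because reads may be shared. UVRAG, a regulator of autophagosome maturation, was at 1.38 (SE 0.39). Of 14 fatty acid synthesis genes, 12 lay below DMSO in both libraries (median -0.91), including the desaturase FADS1 (-1.29, SE 0.44), the acyl-CoA synthetase ACSL3 (-0.88, SE 0.37) and LPIN1 (-0.92, SE 0.40). No lysosome or fatty acid gene passed over the list alone, and no gene of these lists passed over all genes. Camera adjusted p-values were 6.2e-04, 0.0012 and 6.1e-04 (each adjusted p = 0.44 with an estimated correlation), and 0 autophagy genes passed over the list alone without DMSO replicate 1 or without DMSO replicate 2. Without YW-LF replicate 1, 14 lysosome and 10 autophagy genes were higher (with 1 autophagy gene lower) and 4 fatty acid genes lower over the list alone, and without YW-LF replicate 2 these counts were 6, 6 and 8.

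Counts of replication-dependent histone genes in these mRNA libraries differed in the direction opposite to the G1/S list. How fully such libraries capture histone transcripts was not tested. Of 14 measured, 11 lay above DMSO in both libraries and 0 below, with a median log2 fold change of 3.54 (2.69 with the length and GC correction). Among these 11 the smallest margins, found after their values were seen, were in YW-LF replicate 1. H3C10 stood there at 0.338 CPM against 0.329 CPM in DMSO replicate 2, and H1-4 at 1.15 CPM against 1.09 CPM in DMSO replicate 1. H2BC5 was at 4.49 ± 1.47 CPM in DMSO and 55.3 ± 41.7 CPM in YW-LF (3.62, SE 0.67), H2AC6 at 4.01 (SE 0.80) and the linker histone gene H1-2 at 3.72 (SE 0.89). Over the list alone 10 were higher and 4 passed in neither direction, with 0 over all genes tested (camera adjusted p = 3.7e-05; adjusted p = 0.55 with an estimated correlation). The median was 1.33 in YW-LF replicate 1 and 4.31 in YW-LF replicate 2, and over the list alone 15 of the 16 members measured without YW-LF replicate 1 were higher, and 6 of the 14 measured without YW-LF replicate 2 (median 1.30 in the latter fit).

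Other lists were higher in YW-LF replicate 2 than in YW-LF replicate 1. The 50 ribosomal protein genes had a median of 0.17 in YW-LF replicate 1 and 1.82 in YW-LF replicate 2, the 35 nuclear-encoded respiratory chain genes 0.12 and 1.36, and the 30 proteasome subunits -0.12 and 1.13. Their leading members were RPS12 (2.72, SE 0.70), RPS19 (1.82, SE 0.53) and RPS13 (2.03, SE 0.61), NDUFA2 (1.62, SE 0.48), COX7A2 (2.44, SE 0.73) and NDUFA4 (2.38, SE 0.74), and PSMA2 (1.38, SE 0.55), PSMD4 (1.11, SE 0.45) and PSMA3 (1.07, SE 0.48). None of the members passed over the list alone or over all genes with 2 YW-LF libraries, whereas 48, 28 and 22 members were higher over the list alone, and 0, 1 and 0 lower, without YW-LF replicate 1. Camera adjusted p-values with both libraries were 2.0e-06, 0.0015 and 0.034 (adjusted p = 0.63, 0.67 and 0.73 with an estimated correlation). Without YW-LF replicate 2 they were 0.219, 0.723 and 0.296, the last with the opposite direction; the proteasome call was also lost without DMSO replicate 2 (0.180) and with the length and GC correction (0.166).

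Of the 13 mitochondrially encoded genes, both YW-LF libraries lay below both DMSO libraries in 7. Their median log2 fold change was -1.62, but they varied between DMSO libraries by as much: the median difference of DMSO replicate 2 from DMSO replicate 1 was 1.70. MT-ATP8, a subunit of ATP synthase, was at 4284 ± 3339 CPM in DMSO and 745 ± 613 CPM in YW-LF (-2.52, SE 0.95), MT-ATP6, whose gene overlaps it, at -2.22 (SE 0.96), and MT-ND1, of complex I, at -1.84 (SE 0.89). None passed over the list alone or over all genes, and the camera adjusted p of 6.2e-04 (adjusted p = 0.61 with an estimated correlation) was 0.282 without YW-LF replicate 1. The median was -0.55 without DMSO replicate 2, -1.04 without YW-LF replicate 1 and -2.55 without YW-LF replicate 2, and in the last fit 12 genes were lower over the list alone.

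Of 22 YAP/TEAD targets, genes controlled by the Hippo pathway, 1 was lower over the list alone: TGFB2, a growth factor, at 149 and 186 CPM in DMSO and 17.1 and 16.9 CPM in YW-LF (-3.30, SE 0.38). AJUBA was at -1.94 (SE 0.49) and ARHGEF17 at -0.87 (SE 0.40). The median was -0.52 (-0.051 without YW-LF replicate 1, -1.19 without YW-LF replicate 2 and -0.29 with the length and GC correction). The camera adjusted p was 0.024 (adjusted p = 0.63 with an estimated correlation), and 0.727 with the opposite direction without YW-LF replicate 1, where 7 members were higher and 3 lower over the list alone (14 lower without YW-LF replicate 2, 2 lower without DMSO replicate 1); with the length and GC correction it was 0.080. The 6 measured metallothionein list members, genes of metal binding and zinc response, had a median of 1.16 with 0 past the threshold over the list alone (5 higher without YW-LF replicate 1 and 2 without YW-LF replicate 2), led by MT1E (1.42, SE 0.42), MT1X (1.28, SE 0.42) and the transcription factor MTF1 (1.05, SE 0.41). Its camera adjusted p of 0.018 (adjusted p = 0.44 with an estimated correlation) was 0.063 without DMSO replicate 1 and 0.078 with the length and GC correction.

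**Figure D3:**
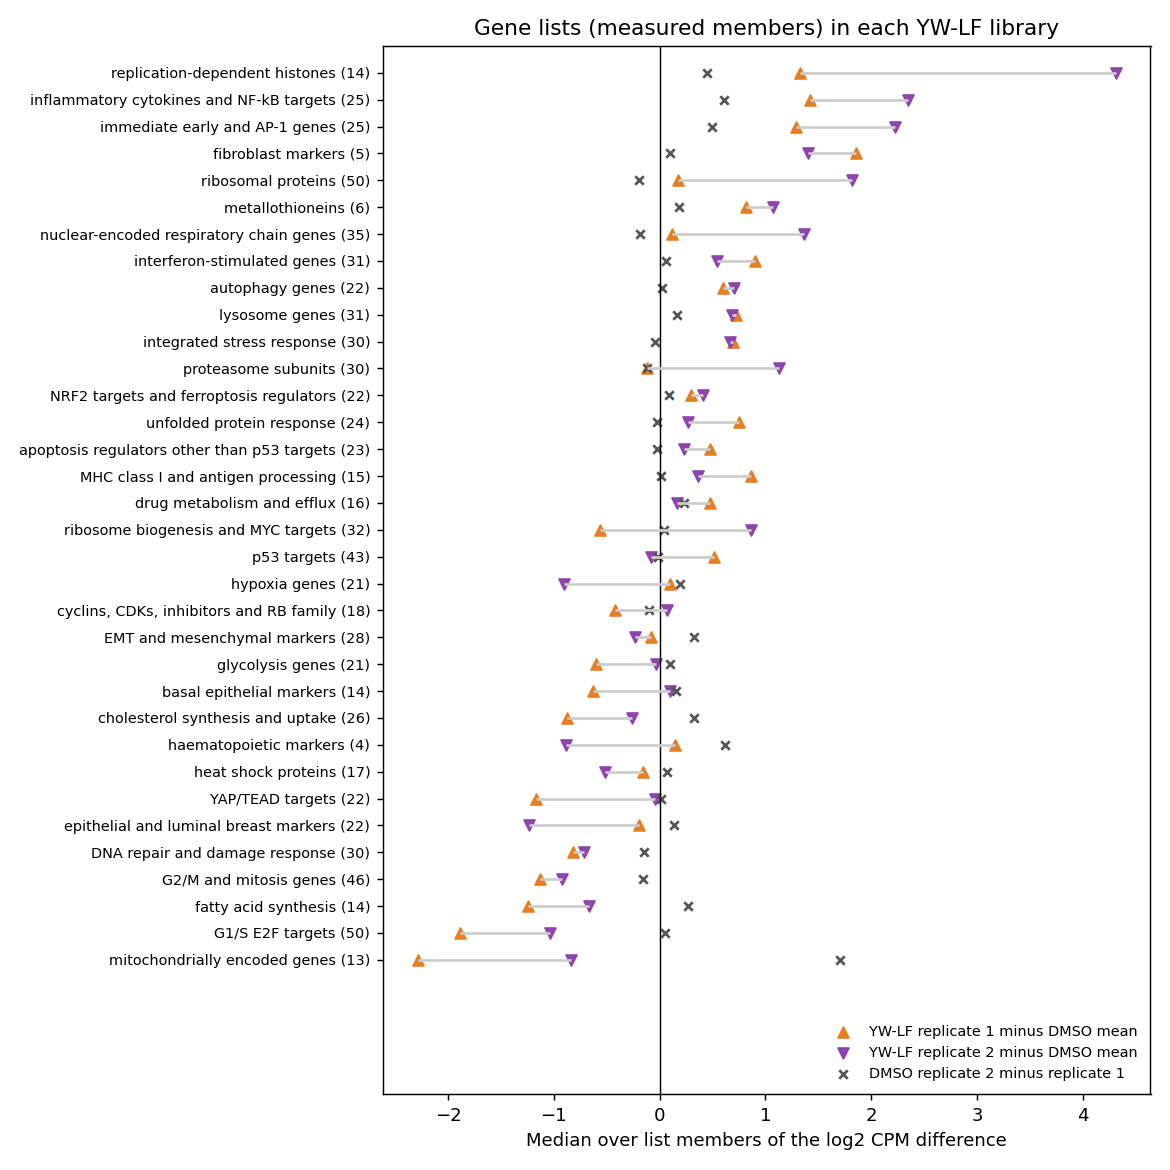
Median log2 CPM difference over the measured members (number in brackets) of each of 34 gene lists, for YW-LF replicate 1 and YW-LF replicate 2 against the DMSO mean (triangles, joined by a grey line) and for DMSO replicate 2 against DMSO replicate 1 (crosses). The G1/S medians are -1.88 and -1.04, while the ribosomal protein medians are 0.17 and 1.82 (the signs of the cyclin and CDK, mesenchymal and hypoxia medians turn with the length and GC correction).

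The genes of lowest p without regard to list, a choice made after seeing the data, included INHBB and INHBA. INHBB, an inhibin and activin subunit, was at 38.0 ± 4.55 CPM in DMSO and 1.04 ± 0.47 CPM in YW-LF (-5.17, SE 0.53), whereas INHBA, another such subunit, was at 1.44 ± 0.22 CPM in DMSO and 21.4 ± 5.19 CPM in YW-LF (3.89, SE 0.49). The others higher were IL1A, PTGS2, GDF15, the protease inhibitor SERPINB2 (3.84, SE 0.41), SDCBP2 (3.85, SE 0.48), SLFN5 (3.07, SE 0.39) and RNF6 (3.22, SE 0.41). The others lower were CCNE2, CLSPN, UHRF1, TGFB2, SERTAD4 (-4.88, SE 0.57), the zinc finger gene ZNF114 (-4.02, SE 0.47) and the keratin KRT80 (-3.15, SE 0.40). All of these had an adjusted p of 0.117 in edgeR.

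Markers of other cell types were mostly below the expression filter. Of 12 haematopoietic markers 4 were measured, with a median of -0.28 (-0.084 without DMSO replicate 2, -2.30 without YW-LF replicate 1 and 0.22 without YW-LF replicate 2), a camera adjusted p of 0.63 and 0 past the threshold over the list alone (1 of the 3 measured without YW-LF replicate 1 was lower). Of 11 fibroblast markers 5 were measured, with a median of 1.37. Over the list alone 1 of these was higher: FAP, chosen after its value was seen, at 0.053 and 0.090 CPM in the DMSO libraries and 0.78 and 9.13 CPM in the YW-LF libraries. The fibroblast list had a camera adjusted p of 0.119, which was 0.019 without DMSO replicate 1 and 0.028 without DMSO replicate 2, and over the list alone 2 of 6 measured members were higher without YW-LF replicate 1 and 2 of 5 without YW-LF replicate 2.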

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

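The tests without mitochondrial genes, with sample quality weights and with the length and GC correction were chosen only after the results were seen. Depth limits genes with few counts, such as MAP1LC3B2 and RSAD2, with at most 7 and 11 counts in a DMSO library. The edgeR counts of 0 genes higher and 0 lower (2830 at an unadjusted p under 0.05) also came from each other scaling, the stricter count filter, limma-voom, robust fitting, the test against a 1.5-fold change, the removal of mitochondrial genes, the length and GC correction and the threshold of 0.01. DESeq2 called 841 higher and 623 lower, of which 1423 genes had an unadjusted p under 0.05 in edgeR; without a filter edgeR called 155 and 120, and limma-voom with sample quality weights 175 and 56. Leaving out 1 library gave 46 to 2963 genes higher, 16 to 2919 lower, and 992 to 7265 at an unadjusted p under 0.05; with 1 library left in a group, that library is assumed to vary like the other group, so the DMSO pair alone sets the spread where a YW-LF library is left out. Beyond that construction, the cause of these differences was not tested.

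Replicate numbers are shared by the groups, but the labels tie them to no batch, and deviations of same-numbered libraries correlated with r = 0.037 across genes. With the replicate number as a block edgeR called 186 higher and 145 lower.

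Camera called 18 of 34 lists, 12 higher and 6 lower. With an estimated correlation or with fry's test of direction it was 0. The estimated form may be unable to call a list with 2 libraries per group, so its 0 calls are not evidence against any list. Fry's mixed test, which asks for change in either direction, called 18, of which 10 were also called by camera. With the estimate, calls were also lost for lists whose correlation lay below the preset 0.01: fatty acid synthesis (0.0057), autophagy (-0.0079) and metallothioneins (-0.043). Higher correlation among members does not explain the loss for these lists. For the other called lists the estimate lay above the preset, as for G1/S (0.287), G2/M (0.098), cytokines (0.218), histones (0.904) and ribosomal proteins (0.963). Their p-values with the preset may therefore be too small, although the estimates also rest on few libraries. For the G1/S and G2/M lists the adjusted p-values were 0.442 with an estimated correlation and 0.0944 in fry's test of direction. In fits that left out 1 library, 10 of the 18 lists passed each time and 8 failed at least once. The p53 list ranged from 0.0133 (without YW-LF replicate 2) to 0.956. The direction turned for YAP/TEAD targets without YW-LF replicate 1 (0.727; range 9.5e-07 to 0.727), for ribosome biogenesis without YW-LF replicate 1 (0.0452; range 0.000928 to 0.970) and for the proteasome without YW-LF replicate 2 (0.296; range 1.1e-05 to 0.296). It also turned, with neither value past the threshold, for hypoxia genes without YW-LF replicate 2 (0.457), for mesenchymal markers without DMSO replicate 2 (0.970) and for haematopoietic markers without DMSO replicate 2 (0.924) or YW-LF replicate 2 (0.585). Of the 75 named genes, 58 passed with DESeq2, and 0 changed sign under another scaling. CDK6 turned without DMSO replicate 2 (-0.057) and YW-LF replicate 2 (-0.63; range -0.63 to 0.69). The cause was not tested.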

Other observations

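The test of histone copies outside the list was chosen only after the result it measures had been seen. Genes named in this part were chosen after their values were seen. Of the 20 genes listed for drug metabolism and efflux, 16 were measured, and 2 were higher over the list alone. TIPARP stood at 90.1 and 86.2 CPM in DMSO and at 575 and 2921 CPM in YW-LF (log2 fold change 4.31, SE 0.89), and CYP1B1 at 29.3 and 36.9 CPM in DMSO and 250 and 146 CPM in YW-LF (2.58, SE 0.44). CYP1A1 (1.81, SE 0.60) and AHRR (1.31, SE 0.71) did not pass, and the transporter ABCC4 (-1.53, SE 0.36) was lower over the list alone. The list median was 0.32 (0.13 without YW-LF replicate 1), and camera gave an adjusted p of 0.27. With DMSO replicate 1 or DMSO replicate 2 left out, 0 members passed over the list alone, against 5 higher and 2 lower without YW-LF replicate 1 and 3 higher and 2 lower without YW-LF replicate 2. In the list of 15 MHC class I genes (median 0.43, or 0.85 without YW-LF replicate 2; camera adjusted p = 0.088) HLA-B was higher over the list alone (2.01, SE 0.37), and 0 passed with DMSO replicate 1 or DMSO replicate 2 left out, against 5 higher and 0 lower without YW-LF replicate 1 and 8 higher and 2 lower without YW-LF replicate 2; genes of this family can share reads. In the list of 22 NRF2 targets and ferroptosis regulators (camera adjusted p = 0.22) 1 was higher over the list alone, OSGIN1 (2.09, SE 0.36). The list median was 0.54, but 0.26 without YW-LF replicate 2 and also 0.26 with the length and GC correction. The number of members passing changed when 1 library was left out.

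The other lists were not called either. Medians were 0.46 for 23 apoptosis regulators (camera adjusted p = 0.15), -0.27 for 26 cholesterol genes (0.076), -0.48 for 17 heat shock proteins (0.12), -0.065 for 28 mesenchymal markers (0.55), -0.60 for 22 epithelial and luminal markers (0.068) and -0.12 for 21 glycolysis genes (0.23). Of 14 basal markers (-0.26, 0.63), SFN was lower (-2.81, SE 0.58) and CDH3 higher (2.95, SE 0.70) over the list alone (0 higher and 1 lower without DMSO replicate 1 or without DMSO replicate 2, 2 higher and 5 lower without YW-LF replicate 1, 3 higher and 7 lower without YW-LF replicate 2), and fry gave the list the direction opposite to camera's. The 21 hypoxia genes had a median of 0.12 but a mean of -0.17, and the 32 ribosome biogenesis and MYC genes a median of 0.22, whereas camera placed both below other genes (0.20 and 0.70). The median of the ribosome biogenesis list was -0.56 in YW-LF replicate 1 and 0.87 in YW-LF replicate 2. These medians depended on single libraries. Without DMSO replicate 1 they were -0.47 for cholesterol genes, -0.32 for heat shock proteins, -0.26 for mesenchymal markers and 0.11 for ribosome biogenesis, and without DMSO replicate 2 -0.16 for cholesterol genes, 0.13 for mesenchymal markers and 0.018 for hypoxia genes. Without YW-LF replicate 1 they were -0.26 for mesenchymal, -1.66 for epithelial (12 members lower and 1 higher over the list alone) and 0.086 for basal markers, -0.92 for hypoxia genes (13 lower and 0 higher), -0.044 for glycolysis genes and 0.86 for ribosome biogenesis (4 lower and 15 higher). Without YW-LF replicate 2 they were -0.91 for cholesterol genes (13 lower and 1 higher), -0.18 for heat shock proteins, -0.11 for mesenchymal, -0.21 for epithelial (6 lower and 2 higher) and -0.87 for basal markers, 0.066 for hypoxia genes (2 lower and 6 higher), -0.61 for glycolysis genes and -0.58 for ribosome biogenesis (10 lower and 0 higher). Of these calls, the cholesterol list passed without DMSO replicate 1 (0.019) and without YW-LF replicate 2 (0.011), the apoptosis list (0.045) and the glycolysis list (0.038) without YW-LF replicate 2, the hypoxia list without YW-LF replicate 1 (0.0063), the epithelial list without DMSO replicate 1 (0.014), DMSO replicate 2 (0.039) or YW-LF replicate 1 (0.013), and the ribosome biogenesis list above other genes without YW-LF replicate 1 (0.045) and below them without YW-LF replicate 2 (9.3e-04).

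YW-LF replicate 2 stood apart from YW-LF replicate 1. Transcript length and GC content explained 9.7% of the variance of their log2 ratio, and 9.6% for the DMSO pair. With that trend removed from the YW-LF ratio only, its SD was still 2.25 times the uncorrected SD of the DMSO pair (2.36 before). Because 1 pair alone was corrected, the fall from 2.36 does not measure a part played by this bias. The remaining ratio argues against this bias as the whole cause in these libraries. The 95% interval of 2.15 to 2.35 came from resampled genes, which are not independent, with 1 pair of libraries per group. It does not cover how such a ratio varies between pairs of libraries. A single response at different strengths was judged by the spread around 1 line through the log2 ratios. That spread was 1.65 times the DMSO SD (1.58 to 1.71 over resampled genes, with the same limit), above a bound of 1.5. The bound takes the YW-LF libraries to be no noisier than the DMSO libraries. Greater noise in YW-LF would also give such a spread, so the ratio does not decide this question. The G1/S median was further from 0 in YW-LF replicate 1, while the ribosomal median was further from 0 in YW-LF replicate 2. The ribosomal protein median of 1.82 in YW-LF replicate 2 lay at percentile 100 among 10000 lists matched on length, GC and expression. The central 95% of those lists ended at 0.92, and their median was 0.61. Matched transcripts in general were thus higher there too, but they do not account for all of the 1.82. In YW-LF replicate 1 the ribosomal median of 0.17 lay at percentile 99.76, so the test marked this list in both libraries. In YW-LF replicate 2 it also marked the respiratory chain (99.99) and proteasome (99.97) lists. Members of matched lists were drawn independently, whereas ribosomal protein genes vary together (estimated correlation 0.963). The percentiles therefore do not measure how often a list of co-varying genes would stand out. A difference in handling, harvest or cell state may remain as the source, and none of these was tested.

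Most measured histone genes lay above DMSO while most G1/S genes lay below. The histone median of 3.54 lay at percentile 100 of matched lists (the central 95% ended at 1.35). Members of those lists were drawn independently, whereas histone genes vary together (estimated correlation 0.904), so the percentile does not measure chance. With the length and GC correction the median was 2.69, which argues against this bias as the whole cause in these libraries. The 14 measured members summed to 44.7 and 52.3 CPM in DMSO and 124 and 585 CPM in YW-LF. Reads moved among these 14 would not give that ratio of at least 2.37 between groups. Over all 65 clustered histone genes of the table the sums were 52.7 and 62.8 CPM in DMSO and 143 and 767 CPM in YW-LF, a ratio of at least 2.281, which argues against reads moved in from copies outside the list; histone sequences outside the table were not analysed here. What raised the histone values is left open, including how fully the mRNA libraries captured histone transcripts, which was not tested. The histone median also differed between the YW-LF libraries (1.33 and 4.31), so a source shared with the divergence of YW-LF replicate 2 may contribute.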
